A study of Mus musculus with 4 samples.

How the data were processed

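Total RNA of mouse bone marrow-derived macrophages was measured on 4 Agilent arrays with 1 colour (Cy3). The arrays fall into 4 groups of 1 array each, by genotype (wild type or Batf2 knockout) and treatment (untreated, or R848 at 100 ng/ml for 8 h), and the groups come from the labels. All 4 arrays lie on 1 slide and were read in 1 scan, so every comparison is within 1 slide.

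The spot intensities were extracted with Agilent Feature Extraction 11.5.1.1, per the file headers and the submitters' processing notes. Per the file headers, the processed signal used here is an intensity on a linear scale from which Feature Extraction had taken the background and a spatial trend within the array, with no normalization between arrays. The headers annotate the probe grid to the mouse build mm9. Each array holds 59305 spots that are not controls, for 56605 probes. The authors also deposited a table of scaled intensity for 39374 spots. Set against the scanner values, each of its columns was the processed signal times 1 factor per array, within 1% for 100.0% of the spots. The factors were 3.72 for wild type untreated, 3.85 for wild type with R848, 4.06 for knockout untreated and 4.13 for knockout with R848, and the column medians were 705, 675, 720 and 685 in the same order. How the factors were set is not given in the sources used here, so what the scale of that table refers to stays unknown. The table also holds the authors' log2 ratios, each of 1 array over another, which the authors deposited beside the intensity columns and which were not used here.

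For the main values, log2 of the processed signal was taken and each array's 75th percentile over all probes that are not controls was subtracted. Spots marked as non-uniform or as population outliers were left out (83 on wild type untreated, 115 on wild type with R848, 76 on knockout untreated and 70 on knockout with R848), and no spot was saturated. Spots of 1 probe were averaged on the log2 scale. A probe counted as well above background on an array where Feature Extraction marked at least 0.5 of its spots so. A probe entered a comparison when it was well above background on at least 1 of the arrays compared. Where the dimmer array was not well above background, its value was set to the lowest value among that array's probes well above background, or to its own where that was higher, and the result is given as "at least N-fold". Such a value also enters the difference between the responses, where it is no bound. A gene was taken at its brightest probe among those well above background on at least 1 array. Of the genes at least 2-fold different that had several measured probes, all probes went the same way for 90.1% of those higher and 83.3% of those lower in the wild-type response, and for 86.9% and 87.5% in the knockout response. The shares were 72.4% and 80.6% between genotypes untreated, 68.0% and 81.0% with R848, and 61.3% and 53.7% for the difference between responses.

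Gene names were taken from the authors' table and updated to the gene table of assembly GRCm38.p6, which served for names and for the order of genes along chromosomes. Of the 56605 probes, 40458 were named: 28867 through an Entrez gene ID, 75 through a current symbol, 45 through a synonym, 10228 through a transcript accession, and 1243 kept the symbol in the file. The other 16147 probes were left unnamed. Named probes stood for 25107 genes, of which 20628 were well above background on at least 1 array.

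With 1 array per group there are no replicates, so no test and no p-value is given, and the number of arrays limits the precision of every value. The spread between 10 spots of 1 probe, over 289 to 292 probes, was 0.074 (SD, log2) for the wild-type response, 0.071 for the knockout response, 0.082 and 0.070 for the genotypes compared untreated and with R848, and 0.099 for the difference between the responses. This spread covers technical error within an array and leaves out the variation between cultures. A gene is called higher or lower at a difference of at least 2-fold. The comparisons were R848 against untreated in each genotype, knockout against wild type at each time, and the knockout's response minus the wild type's. For 35 gene lists fixed before the data were examined, the median log2 difference was set against 10000 random lists of the same size matched on mean expression in 20 bins. Its percentile describes these arrays and is no test of the conditions. A list is said to stand apart outside the central 95% of the random lists.

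Genes were named by a rule fixed before the data were examined. It takes Batf2 and 12 cytokine and regulator genes in every comparison. In each comparison it takes the 10 largest increases and the 10 largest decreases measured on all arrays compared. For these, all measured probes go the same way and the brighter array is at or above its 75th percentile. It adds up to 5 of the largest lower bounds per direction and members of the gene lists. Genes with a provisional symbol, such as one ending in Rik or starting with BC and a digit, were left out of the ranking. Among those left out, BC018473 stood at -6.06 between genotypes untreated and -6.79 with R848, beyond Mcpt8 at -5.56 and -5.64. Genes near Batf2 on its chromosome, within 5 Mb, were compared as a check for DNA carried along with the targeted allele. A gene set induced or repressed by R848 was chosen on the mean response of both genotypes, so that the choice was symmetric in genotype.

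After the values were seen, areas of an array were marked in which a spot's 8 nearest spots differed by a median of at least 1 log2 from the other 3 arrays. They held 270 spots on wild type untreated, 245 on wild type with R848, 312 on knockout untreated and 177 on knockout with R848, against 20, 24, 24 and 11 with positions shuffled. Genes whose probe lies in such an area are named as such.

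The steps were tested on simulated data. In simulated R848 against untreated arrays of the wild type with 19758 genes, 50 genes changed by each of 1.5, 2.5, 4 and 8-fold were recovered at medians of 1.51, 2.48, 4.05 and 8.11-fold. All 50 genes at each of 2.5, 4 and 8-fold were called, against 0 of 50 at 1.5-fold and 0 of 19558 unchanged genes. The changed genes were drawn from those clearly above background in untreated wild type, and the medians used those measured on both arrays. Their recovery therefore says nothing on dimmer genes. The simulated arrays were copies of 1 array with the same noise for dim and bright genes, about the size of the spread between spots of 1 probe. They hold no variation between cultures, so the 0 calls among unchanged genes say nothing on false calls between the real arrays. Of 100 lists of 20 genes drawn at random from all simulated genes, 5 stood apart. In a simulated bright area on the knockout array with R848, 36 of 40 raised spots were found together with 8 others.

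The alternatives tried were quantile normalization, the 75th percentile over probes well above background on all arrays, median centring, normexp background correction (offset 50), the authors' table, probes well above background on every array compared, no filter and no lower bounds (1 alternative), the mean over a gene's probes, a 3-fold threshold, and outlier spots kept. Genes above the 75th percentile alone, and leaving out spots in the marked areas, were added after the data were seen. The scanner files hold a median and no mean spot signal among the columns used here, so normexp ran on the median signal and the median local background. Its offset of 50 is added to every signal and shrinks the differences of dim genes by arithmetic. Median centring moved the median of all genes by over 0.1: from -0.03 to 0.13 in the wild-type response and from -0.06 to 0.09 in the knockout response. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.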

Results

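Macrophages grown from mouse bone marrow with macrophage colony-stimulating factor were compared between wild-type and Batf2-deficient male mice, both on the C57BL/6J background. Batf2 is a basic leucine zipper transcription factor of the AP-1 family. R848 (resiquimod) is a small molecule that activates the endosomal receptor TLR7 in mouse cells. The 4 arrays were wild type untreated, wild type after 8 h with R848 at 100 ng/ml, knockout untreated and knockout after 8 h with R848. Each group had 1 array, so none of the differences below has a replicate check. Of the probes, 69.6%, 60.6%, 71.4% and 64.9% were well above background in that order, and the 75th percentile of the signal was 278, 265, 262 and 252.

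Batf2 was read by 1 probe. In wild-type cells its signal was 34.1 untreated and 94.8 with R848, a rise of 2.91-fold. In knockout cells it was 26.7 untreated and 10.8 with R848, and the last of these was not well above background. With R848 the knockout value was therefore at least 6.20-fold lower than the wild-type value, whereas the untreated arrays differed by 1.21-fold. Batf2 sits on chromosome 19, and where the probe lies relative to the deleted part of the gene is not given in the sources used here, so its untreated value does not check the genotype label. Under normexp background correction the wild-type response of Batf2 was 0.72 on the log2 scale, below 2-fold, and the difference between genotypes with R848 was -1.05. That setting adds an offset of 50 to every signal, more than the untreated wild-type signal of 34.1. The offset shrinks differences between dim signals by arithmetic, so the 0.72 does not decide for or against a 2-fold rise.

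The comparison of R848 with untreated cells asked what 8 h of TLR7 stimulation changes in wild-type macrophages. Il12b, which encodes a subunit shared by IL-12 and IL-23, rose 262-fold, the neutrophil attractants Cxcl2 and Cxcl1 rose 233-fold and 190-fold, and Cxcl3 rose at least 343-fold. Il6 rose 159-fold, Il1b 106-fold, Tnf 28.0-fold and the anti-inflammatory cytokine Il10 22.4-fold. Acod1, the enzyme that makes itaconate, rose 139-fold, the cytokine-signalling inhibitor Socs3 95.9-fold, the metalloprotease Adamts4 102-fold, the receptor Tarm1 87.3-fold and the scavenger receptor Marco 67.2-fold.

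By gene list, 11 of 16 inflammatory cytokines rose in wild-type cells (list median 2.11 on the log2 scale), as did 3 of 4 IL-12 family genes (median 2.47), 12 of 19 chemokines (median 2.55) and 16 of 21 NF-kB components and feedback inhibitors (median 2.5). Of the IL-12 family, Il12a rose 4.82-fold and Ebi3 by 2.66 on the log2 scale, and Il23a was well above background on the wild-type untreated array alone and has no response value. Type I interferon-stimulated genes rose in 29 of 32 cases (median 2.23), led by Ifit1 at 4.07, Mx1 at 3.57 and Isg15 at 3.57. Among interferon-gamma-inducible GTPases and regulators 10 of 16 rose (median 1.23), with Gbp2 at 4.19 and Gbp3 at 3.77, and Irf8 fell by 1.04. The immunometabolism list had a median of 3.08 with 12 of 15 genes higher, among them the cystine transporter Slc7a11 at 4.42 and the mitochondrial superoxide dismutase Sod2 at 4.32, while Nos2, the inducible nitric oxide synthase, stood at -0.07. Targets of the oxidative stress factor NRF2 rose in 9 of 10 cases (median 1.37, Txnrd1 1.84). Of the costimulation and checkpoint genes 7 of 12 rose (median 1.53), with Cd40 at 3.84 and the PD-1 ligand Cd274 at 2.86. Heat shock genes had a median of 0.63, inflammasome genes 0.35 with Nlrp3 at 2.58, and glycolysis genes 0.32 with 0 of 18 past 2-fold. For all of these lists the median lay above the central 95% of random lists. Inside that range were inflammasome genes under quantile normalization (0.24) and with the mean over probes (0.31), and glycolysis genes with the mean over probes (0.20).

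Proliferation genes were lower after R848 in wild-type cells. The mitosis list had a median of -0.91 with 7 of 22 genes at least 2-fold lower, among them the kinase Cdk1, which fell by at least 2.01 on the log2 scale, and Kif11 at -1.40. DNA replication genes had a median of -0.80 with 8 of 23 lower, including Rrm2 at -1.52. Lysosomal genes had a median of -0.49, macrophage identity genes -0.35 with the efferocytosis receptor Mertk at -2.50, targets of the sterol receptor LXR -0.64 with the cholesterol exporter Abcg1 at -1.59, and MHC class II genes -0.40. Outside the lists, the transporter Slco2b1 fell 93.4-fold at its brightest probe, although its 2 measured probes differed with an SD of 4.19. The G protein regulator Rgs2 fell 15.2-fold, Tmem37 14.7-fold, the RING finger gene Rnf150 14.1-fold, Cmbl 13.5-fold and the ectonucleotidase Entpd1 by 3.70 on the log2 scale.

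In all, 1162 genes were at least 2-fold higher and 1316 at least 2-fold lower with R848 in wild-type cells, of 18763. Median centring gave 1515 higher and 969 lower, a share of 61.0% higher in place of 46.9%, and normexp gave 702 and 575. Among the named lower bounds, Hormad1, Gchfr, Bmp5, Pde5a and Sox11, and among the measured values Bbs10, lie in or beside bright areas of 1 array. They are within these counts but are not read as responses, and with marked areas left out the counts were 1139 and 1246.

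The same comparison in knockout cells asked which of these responses occur without Batf2. The acute phase gene Saa3 rose 961-fold, Cxcl2 369-fold, Marco 362-fold, Cxcl1 337-fold, Acod1 279-fold and Clec4e, the C-type lectin Mincle, 191-fold. Cytokines rose as well: Il1b 161-fold, Il12b 134-fold, Tnf 49.1-fold, Il10 12.6-fold, Il12a by 3.17 on the log2 scale, Il6 at least 261-fold and Cxcl3 at least 650-fold. Cxcl10, a chemokine induced by interferon, rose at least 68.5-fold. Among the lower genes Rnf150 fell 32.4-fold, Rgs2 14.8-fold, Lpar6 13.1-fold, Bex1 13.1-fold and Entpd1 11.2-fold. At its brightest probe Slco2b1 fell at least 173-fold, but its 2 probes had differed widely in the wild-type response (SD 4.19).

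Interferon-stimulated genes rose in 31 of 32 cases in knockout cells (median 2.95), with Ifit1 at 6.24, Mx1 at 5.75 and Oasl1 at 5.53. The interferon-gamma-inducible list rose in 12 of 17 cases (median 2.04). Chemokines rose in 12 of 19 (median 2.46), inflammatory cytokines in 10 of 17 (median 1.83, with Osm at -1.08), IL-12 family genes in 3 of 4 (median 2.80), NF-kB components in 16 of 21 (median 2.35), immunometabolism genes in 12 of 16 (median 2.51) and NRF2 targets in 9 of 10 (median 1.61). Cholesterol biosynthesis genes had a median of 1.0 with 10 of 20 higher, led by Sqle at 1.71, whose probe lies in a marked area of the wild-type untreated array, and Fdps at 1.41. The list stood at 0.53 in wild-type cells with 1 of 20 higher. MHC class I and antigen processing genes had a median of 0.81 with 6 of 14 higher, such as the peptide transporter Tap1 at 2.22, against a median of 0.30 with 3 of 14 in wild-type cells. Costimulation genes rose in 6 of 13 (median 0.72), heat shock genes had a median of 0.68 and glycolysis genes 0.28. Mitosis genes had a median of -1.13 with 13 of 22 lower, DNA replication genes -0.52 with 4 of 23 lower, macrophage identity genes -0.43, lysosomal genes -0.36, LXR targets -0.35 and MHC class II genes -0.38. All of these medians lay outside the central 95% of random lists. Inside it were glycolysis genes (0.16) and MHC class II genes (-0.31) with the mean over probes, LXR targets with that mean (-0.31) and under quantile normalization (-0.32), and costimulation genes with probes well above background on every array (0.32).

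In knockout cells 1357 genes were higher and 1304 lower with R848, of 19840. Median centring gave 1671 higher and 977 lower, 63.1% higher in place of 51.0%, and normexp gave 810 and 547. Across the 18457 genes measured in both responses, the log2 changes of the genotypes had a Pearson r of 0.78 and a Spearman rho of 0.67. These responses share no array, and genes are not independent replicates. Higher in both were 777 genes, against 70.6 for independent lists, lower in both 669 against 80.9, and 11 went in opposite directions.

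**Figure D1:**
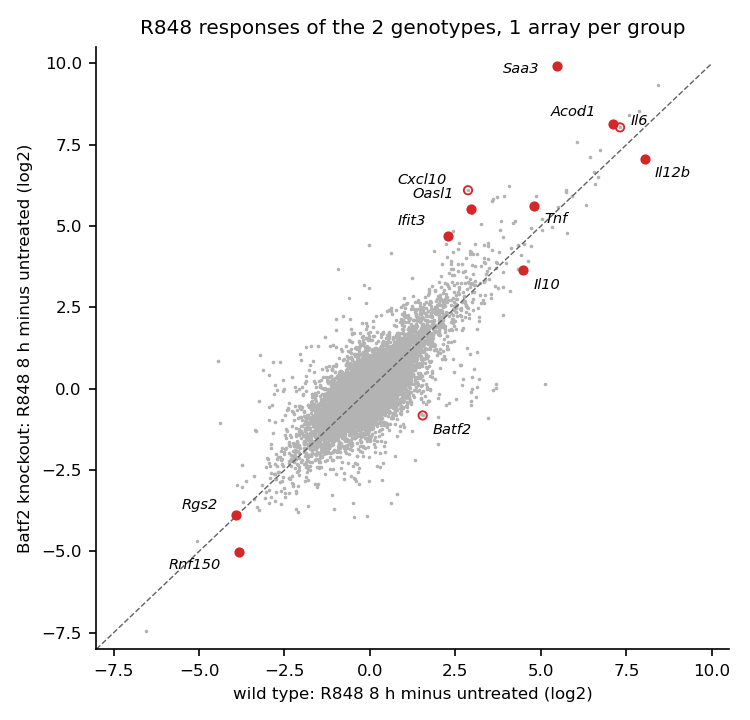
Each point is a gene, with the log2 difference between R848 and untreated in wild type on the horizontal axis and in Batf2 knockout on the vertical axis, 1 array per group; red points are named genes, open where a value is a lower bound, and the dashed line marks equal responses. Most genes lie along the line (r of 0.78), with Saa3, Cxcl10, Oasl1 and Ifit3 above it and Il12b, Il10 and Batf2 below it.

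Knockout and wild-type cells were then compared before treatment, which shows where the cultures differed without R848. Transcripts of basophils, mast cells and granulocyte precursors were much lower in the knockout. The basophil protease Mcpt8 was 47.0-fold lower and Prss34 21.7-fold lower, and the granule proteins Ctsg, Mpo and Elane of early granulocytes were 16.2-fold, 14.8-fold and 12.0-fold lower. The glutamate receptor gene Gria3 was 24.6-fold lower, the progenitor genes Ms4a3 and Plac8 8.05-fold and 7.59-fold lower, and Saa3 23.2-fold lower. Of 9 measured mast cell and basophil markers 7 were lower (median -2.83, including the stem cell factor receptor Kit at -2.69), and of 14 granulocyte markers 6 were lower (median -0.94).

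Interferon-stimulated genes were lower in untreated knockout cells, with 11 of 31 at least 2-fold lower and 0 higher (median -0.59). Irf7, a transcription factor of the interferon response, stood at -2.48, Oasl1 at -2.02, Ifit3 at -1.89 and Mx1 at -1.46. The interferon-gamma-inducible list had a median of -0.35, MHC class I genes -0.39, inflammasome genes -0.17, chemokines -0.17 and IL-12 family genes -0.49. MHC class II genes, which present peptides to helper T cells, were lower in 6 of 10 cases (median -1.07, H2-Eb1 -1.33 and Cd74 -1.12). Costimulation genes were lower in 5 of 11 (median -0.92, Cd40 -1.21, Cd86 -1.08), erythroid and megakaryocyte markers in 4 of 12 (median -0.52, Ppbp -1.51) and alternative activation genes in 3 of 14 (median -0.32, Clec10a -1.47). DNA replication genes had a median of -0.46, mitosis genes -0.35 and cholesterol biosynthesis genes -0.17, with 0 members past 2-fold in each of these lists. Higher medians were seen for lysosomal genes (0.26), immunometabolism genes (0.27) and macrophage identity genes (0.20), although Cd163 stood at -2.34 and Cx3cr1 at -1.67. These medians lay outside the central 95% of random lists, whereas NF-kB components had a median of 0.02 at percentile 39.2, with the adaptor Traf1 at -1.52. Inside the random range were the interferon-gamma-inducible list with the mean over probes (-0.12), costimulation genes with no filter on dim probes and no lower bounds (-0.19) and IL-12 family genes under normexp (-0.16), in the authors' table (-0.26) and with probes well above background on every array (-0.30). So were macrophage identity genes under quantile normalization (0.14) and with the mean over probes (0.15), cholesterol genes under normexp (-0.071) and with marked areas left out (-0.090), and inflammasome genes under normexp (-0.13).

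In untreated knockout cells Bex1 was 3.57-fold higher, the immunoglobulin gene Iglv1 3.18-fold, Adgrb1 2.88-fold, Vsig8 2.87-fold, the guidance factor Ntn1 2.80-fold, the presynaptic gene Bsn 2.78-fold and the integrin gene Itgax 2.77-fold. Neurod2 (7.79-fold) and Fgf16 (at least 23.7-fold) were high on the untreated knockout array alone, and Cdhr5, Abcb8, Bbs10, Bmp5, Pde5a and Sox11 lie in or beside marked areas. In all, 569 genes were higher and 646 lower, of 20301. Among genes above the 75th percentile the counts were 64 and 201, and normexp gave 111 and 219, a share of 33.6% higher in place of 46.8%.

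The comparison of genotypes with R848 asked which transcripts depend on Batf2 in stimulated cells. Cytokines that R848 induced were for the most part close in the 2 genotypes: Il6 differed by 0.21 on the log2 scale, Tnf by 0.31, Il1b by 0.21 and Il12a by 0.23. Il12b was 2.10-fold lower and Il10 2.26-fold lower in the knockout. Cxcl10 was 3.09-fold higher and the fungal pattern receptor Clec7a 2.84-fold higher. Irf1, a transcription factor of the interferon-gamma response, stood at 0.86, Ifnb1 at 0.67, Nos2 at 0.45, Batf3 at -0.32 and Batf at -0.57, and the Batf probe lies in a marked area of the knockout array with R848. Il23a was not well above background on either array.

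By list, interferon-stimulated genes had a median of 0.22 with 2 of 32 higher (Rsad2 1.23 and Mx2 1.0), the interferon-gamma-inducible list 0.49 with 2 of 17 higher, namely Gbp6 at 1.04 and Gbp4 at 1.04 as a lower bound, and chemokines 0.25 with Ccl7 at 1.27 and Ccl8 at -1.31. Immunometabolism genes had a median of 0.36, NRF2 targets 0.36 with the glutathione synthesis enzyme Gclc at 1.07, lysosomal genes 0.30 and cholesterol biosynthesis genes 0.24. NF-kB components stood at -0.18, with the phosphatase Dusp2 at -1.03, genes of the unfolded protein response at -0.27, DNA replication genes at -0.19 and mitosis genes at -0.59 with 4 of 22 lower. MHC class II genes had a median of -0.75 with 2 of 10 lower, alternative activation genes stood at -0.47 and monocyte and dendritic cell markers at -0.19. Each of these medians lay outside the central 95% of random lists, whereas inflammatory cytokines had a median of 0.21 at percentile 96.0. Inside the random range were chemokines with no filter and no lower bounds (0.12), and alternative activation genes and monocyte and dendritic cell markers in the authors' table (-0.049 and -0.057) and with probes well above background on every array (-0.077 and -0.085). The basophil and precursor transcripts were low with R848 too. Prss34 was 21.1-fold lower, Ctsg 11.1-fold, Mpo 9.22-fold, Mcpt8 at least 49.9-fold and Gria3 at least 19.5-fold, with 6 of 9 mast cell and basophil markers (median -2.42) and 6 of 15 granulocyte markers (median -0.84) lower.

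Iglv1 was 6.52-fold higher with R848 in the knockout, Shisa4 4.45-fold, Vsig8 3.05-fold, Sppl3 2.81-fold and Tacc2 2.78-fold, while Zdhhc24 (7.97-fold) and Ccdc96 (at least 25.0-fold) were high on this array alone. Vsig2 (3.36-fold) and Fabp7 (2.83-fold) lie in marked areas. Of the 10 largest measured decreases under the naming rule, 6 lie in or beside bright areas of the wild-type array with R848 (Dffa, Gfod1, Nkpd1, Wdr17, Fhit and Epm2aip1). So do Hormad1, Gchfr and Vmn2r76 among the lower bounds, and the 2 probes of St6galnac2 disagreed (SD 2.30). In all, 440 genes were higher and 459 lower, of 18768. Among genes above the 75th percentile the counts were 90 and 136, and the authors' table gave 486 and 321, 60.2% higher in place of 48.9%.

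The differences between genotypes before and after R848 had a Pearson r of 0.40 and a Spearman rho of 0.35 across 18463 genes. Higher at both times were 36 genes against 7.16 for independent lists, lower at both 176 against 11.4, and 15 went in opposite directions. Genes within 5 Mb of Batf2 on chromosome 19 differed by a median size of 0.23 untreated (255 genes) and 0.20 with R848 (240 genes), at percentiles 50.4 and 63.2 of random lists. Of them 3 were higher and 6 lower untreated, and 3 were higher and 2 lower with R848.

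**Figure D2:**
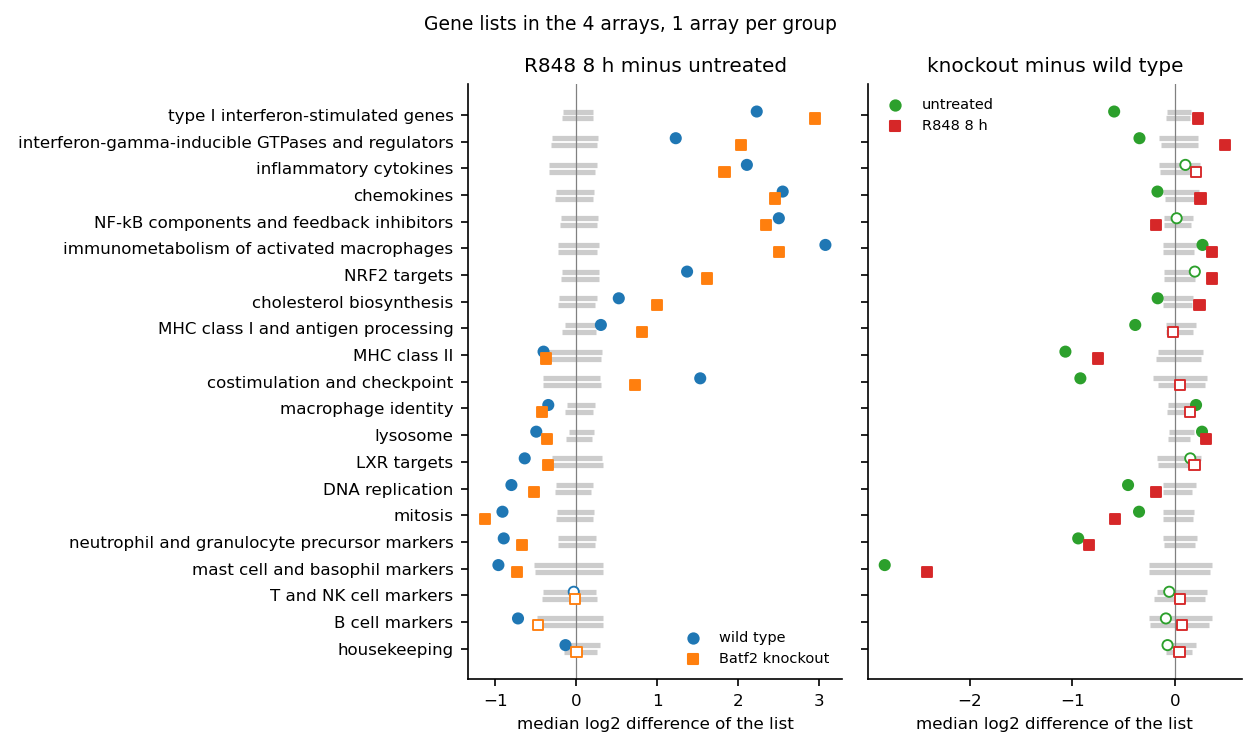
Median log2 difference of 21 gene lists, for R848 against untreated on the left (circles wild type, squares knockout) and knockout minus wild type on the right (circles untreated, squares R848), 1 array per group; grey bars span the central 95% of matched random lists, and filled symbols lie outside them. Interferon-stimulated genes stand at -0.59 untreated and 0.22 with R848 in the right panel, and mast cell and basophil markers at -2.83 and -2.42.

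The response to R848 in the knockout minus that in the wild type was taken gene by gene. Interferon-stimulated genes showed the larger increase in the knockout, where 13 of 32 had a response at least 2-fold larger and 0 a smaller one (median 0.87). Oasl1 responded 5.99-fold more, Ifit3 5.42-fold, Ifit2 5.37-fold, Ifi206 5.30-fold and Slfn1 5.15-fold, and Cxcl10 stood at 3.23 with an untreated knockout value not well above background. Saa3 responded 21.6-fold more and Marco 5.39-fold. For these genes the untreated knockout value was lower than the wild-type value (Saa3 -4.53, Marco -2.12, Ifi206 -2.37), and with R848 the genotypes were close for Saa3 at -0.10, Marco at 0.31 and Ifi206 at 0.03.

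Other lists with a positive difference between the responses, outside the central 95% of random lists, were interferon-gamma-inducible genes (median 0.88, 5 of 17), cholesterol biosynthesis (0.46), MHC class I (0.42), interferon regulatory factors (0.38), chemokines (0.38), costimulation (0.29), inflammasome genes (0.22), the AP-1, BATF and MAF family (0.19) and erythroid markers (0.49). Granulocyte markers (0.29) had negative responses in both genotypes, with medians of -0.90 in wild type and -0.67 in the knockout. Mitosis genes stood at -0.24. Under normexp the AP-1 family, costimulation and mitosis were inside the random range at 0.035, 0.14 and -0.081, as were the AP-1 family and costimulation with the mean over probes (0.099 and 0.23) and costimulation in the authors' table (0.27). Of 17 inflammatory cytokines 3 had a response at least 2-fold smaller in the knockout, namely Tnfsf15 at -1.60 with a wild-type untreated value not well above background, Edn1 at -1.33 and Il1rn at -1.30, and 0 a larger one. Il12b stood at -0.96 and Il10 at -0.83, against 0.81 for Tnf, 0.90 for Il12a and 0.61 for Il1b, all short of 2-fold, and Irf1 stood at 0.85. In all, 747 genes had a response at least 2-fold larger and 863 at least 2-fold smaller in the knockout, of 20628. Of these, 338 and 513 were not well above background on every array, so their values rest on the lowest value set there. Among genes measured on all arrays 409 were larger and 350 smaller. Of the 10 measured genes with the largest decrease under the naming rule, 7 lie in or beside marked areas. The others were Neurod2, Entpd7 (4.19-fold) and B3gnt5 (3.84-fold). The counts among genes above the 75th percentile were 158 and 81. The authors' table gave 643 and 457, 58.5% larger in place of 46.4%.

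R848-responsive genes were also compared as sets chosen on the mean of both responses. The 1018 induced genes were at a median of 0.13 in the knockout relative to wild type with R848, where 53 were higher and 65 lower. Untreated, 969 of them had a value and stood at -0.07, with 20 higher and 81 lower. The 1048 repressed genes stood at 0.06 with R848 and 0.02 untreated, at percentiles 99.7 and 1.78 of random lists. Random lists had medians from 0.01 to 0.05 and from 0.02 to 0.07 for the induced set at these times. With R848 the induced set stood at 0.050 under median centring, and with no filter and no lower bounds it stood at 0.20 and the repressed set turned to -0.063. The repressed set untreated stood at 0.13 under normexp.

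**Figure D3:**
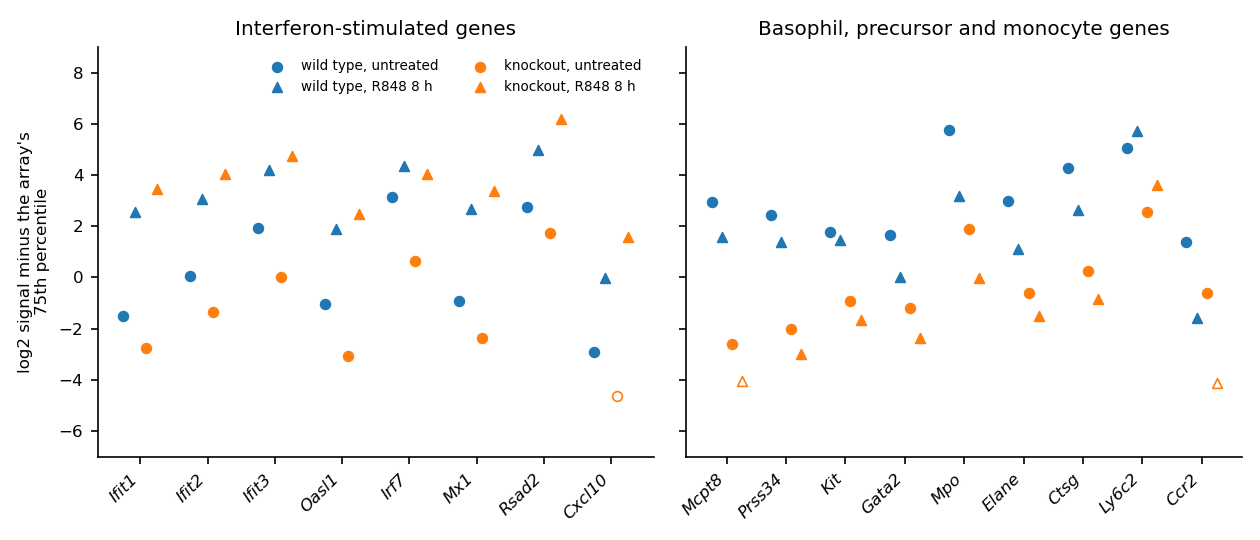
Log2 signal minus the array's 75th percentile on each of the 4 arrays for interferon-stimulated genes (left) and for basophil, precursor and monocyte genes (right); circles are untreated and triangles R848 at 8 h, blue wild type and orange knockout, open where the value was not well above background. The genes of both panels are a selection. The untreated knockout values of the interferon-stimulated genes shown lie below those of wild type (Irf7 -2.48). In the whole interferon-stimulated list, which leaves out Cxcl10, 11 of 31 were at least 2-fold lower untreated (median -0.59). Both knockout values of Mcpt8, Prss34 and Mpo lie below both wild-type values.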

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

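Of the tests here, those on whether other probes of a gene follow and on distances between spots were set before their results were seen; the count of spots lying together, and all tests on basophil and precursor genes and on untreated interferon-stimulated genes, were chosen after. The size of 0.5 on the log2 scale that singles out genes moving in opposite directions was also chosen after seeing the values. None of the differences between genotypes or times was tested, since each group has 1 array. The bootstrap intervals given below resample genes within these arrays, so they hold no variation between arrays or cultures.

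With R848, several genes moved in opposite directions in the genotypes. Adgrb1 stood at -0.76 in the knockout and 0.68 in wild type, Batf2 at -0.82 (a bound) and 1.54, and Itpr1, whose probes differ with an SD of 1.06, at 0.86 and -1.66. Vsig2 stood at 0.80 and -0.67 with its probe in a marked area, Zdhhc24 at 2.79 and -0.62 on a probe high on 1 array alone, and Pde5a at 0.86 and -4.44 with its probe in a bright area of the wild-type untreated array.

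Between the times, the difference of knockout from wild type turned from lower untreated to higher with R848 for 4 lists that stood apart from random lists at both times. Interferon-stimulated genes went from -0.59 to 0.22, interferon-gamma-inducible genes from -0.35 to 0.49, chemokines from -0.17 to 0.25 and cholesterol biosynthesis genes from -0.17 to 0.24. For 3 of them 1 time lay inside the random range under another setting: cholesterol genes untreated under normexp (-0.071) and with marked areas left out (-0.090), interferon-gamma-inducible genes untreated with the mean over probes (-0.12), and chemokines with R848 with no filter and no lower bounds (0.12). Single genes did the same: Cxcl10 from -1.60 (a bound) to 1.63, Ifit2 from -1.43 to 1.0, Ifit3 from -1.89 to 0.55, Oasl1 from -2.02 to 0.56 and Slfn1 from -1.24 to 1.13. Rnf150 went the other way, from 0.60 to -0.60.

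Outside the named genes, 140 of 16147 unnamed probes were at least 2-fold higher with R848 in both genotypes, and 74 of these have coordinates in the files. The probe at chromosome 16, 84702353 to 84710928 (build mm9, marked R in the file) rose by 5.72 in wild type and 5.66 in knockout on the log2 scale. A probe at chromosome 13, 15947521 to 15999246 (mm9), rose by 4.33 and 3.53.

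Interferon-stimulated genes lower in the untreated knockout were weighed against technical causes. Under the 6 scalings tried the list median stayed between -0.63 and -0.49, which argues against scaling between arrays. Genes induced at least 4-fold by R848 in both genotypes and outside the interferon lists had a median of -0.20 untreated (182 genes, bootstrap interval over genes -0.26 to -0.06). They were thus lower too, the direction that general Toll-like receptor activation of the untreated wild-type culture would give. They were chosen on responses that subtract the same untreated values, so genes already raised in untreated wild type tend to drop out. The test therefore cannot decide for or against such activation. Lower resting interferon signalling in knockout cells may account for the list median of -0.59. With 1 culture per genotype it cannot be told apart from a difference between cultures.

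Basophil, mast cell and granulocyte precursor transcripts were lower in the knockout. Of the 13 members at least 2-fold lower untreated, 76.9% were also lower on the separate pair of R848 arrays, which argues against noise of 1 array. The share was 34.2% for all genes lower untreated, which were not matched on brightness. Each gene was read at the same probe on every array, so a fault of a probe would repeat and was not weighed by this. Markers of T, NK, B, stromal, erythroid and megakaryocyte cells were chosen for being at least 1 log2 above the floor in untreated wild type. They had a median of -0.10 (44 genes, bootstrap interval over genes -0.25 to 0.088). That choice does not show that the signals came from such cells, and signal from another source would not follow their number. The median therefore cannot decide for or against more of every other cell type alike in the wild-type cultures. Erythroid and megakaryocyte markers alone stood at -0.52 untreated and 0.03 with R848. A larger number of basophil, mast cell and granulocyte precursors in the wild-type cultures may account for the medians of both lists together, -1.13 untreated and -1.0 with R848. An effect of Batf2 on these cells and a difference between cultures cannot be told apart with 1 culture per genotype.

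For 31 genes 1 array alone was at least 4-fold above each of the other 3, and 14 of them were high on the wild-type array with R848. Their spots lay at a median distance of 2.24 grid positions from the nearest other such spot, where the lower limit of the central 95% of random draws was 30.7, which is consistent with damaged areas on some of the arrays. For 20 of the 31 another such spot lay within 5 positions (13 of 14 on wild type with R848, 5 of 8 on wild type untreated, 2 of 5 on knockout untreated and 0 of 4 on knockout with R848), where 4 was the upper limit of the central 95% of random draws, which argues against a transcript change for those genes. Of the genes' 13 other measured probes 23.1% were also high on that array, against 82.4% that followed for genes induced at least 4-fold in both genotypes, and this share decides neither for an artefact of the spot nor for a change of the whole transcript. Of the genes with no such neighbour, Pde5a and Abcb8 lie in or beside marked areas. Mpo, whose 2 probes agreed untreated (SD 0.10), was lower in the knockout at both times. Nkg7 was so too (-2.73 untreated and -1.87 with R848). St6galnac2 was also lower at both times (-2.80 and -3.56), but its probes disagreed with R848. It stays open with the remaining genes, Neurod2, Fgf16, Zdhhc24 and Ccdc96 among them.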

How the results depend on the processing

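No paired analysis was possible because each group has 1 array. Values for genes above the 75th percentile alone and with spots in marked areas left out were chosen after seeing the data; the other alternatives were fixed before. A value counts as moved when it changes by more than the spread between spots of 1 probe, a correlation by more than 0.1 and a count by more than 1.5 times. That spread comes for the most part from bright probes. Changes of sign were counted only for values called in the main setting. Of 3447 values of lists and named genes, 2729 stayed within that spread, 714 moved by more and 4 called values changed sign. These were the housekeeping list in the wild-type response (0.020 under median centring), Hormad1 between genotypes with R848 (0.37 in the authors' table), and Gfod1 with marked areas left out (0.028 between genotypes with R848 and 0.82 for the difference between responses), the last in keeping with its place in a bright area. The counts and values that follow are in the order wild-type response, knockout response, genotypes untreated, genotypes with R848 and difference between responses, higher before lower, and the cause was not tested unless stated. Under normexp the counts were 702 and 575, 810 and 547, 111 and 219, 104 and 148, and 186 and 159. The offset of 50 added there is near the arrays' median processed signals of 51.7 to 61.5. It therefore shrinks the differences of dim genes, and so counts and list medians, by arithmetic. How much of each change under normexp comes from the offset was not tested. At 3-fold the counts were 533 and 443, 673 and 454, 146 and 240, 104 and 165, and 256 and 280, through the stricter threshold itself. Among genes above the 75th percentile they were 713 and 605, 793 and 526, 64 and 201, 90 and 136, and 158 and 81, from fewer genes. With no filter on dim probes and no lower bounds, changed together, the lower genes were 2263 and 2281 in the responses, and the counts were 1487 and 1181 untreated, 1376 and 840 with R848, and 1730 and 1764 for the difference, where values near background enter and replace the bounds. The correlation of the responses was then 0.54 and that of the genotype differences 0.21. With probes well above background on every array compared, higher genes were 323 untreated and 259 with R848, and the difference gave 409 and 350, from fewer genes. The authors' table gave 457 genes with a smaller response in the knockout. Batf2 stood at 1.66, -0.62 and -0.36 in the wild-type response, knockout response and untreated comparison under quantile normalization, and at 1.69 and -0.68 in the responses under median centring. Under normexp it stood at 0.72, -0.22, -0.10, -1.05 and -0.94 in the 5 comparisons, and with no filter at -1.25 in the knockout response, -3.06 with R848 and -2.79 for the difference. The authors' table gave no Batf2 value. R848-induced genes with R848 stood at 0.050 under median centring and 0.20 with no filter. R848-repressed genes stood at 0.13 untreated under normexp and turned to -0.063 with R848 with no filter. Outlier spots kept, the mean over a gene's probes and the percentile over probes well above background on all arrays left the counts within 1.5 times. Of 139 named values past 2-fold, 139 stayed past it in the same direction under quantile normalization and median centring, 138 under normexp and 134 with the mean over probes. Under normexp 156 named values nevertheless moved by more than the spread and 20 stayed within it. Of 122 with a value 114 stayed past 2-fold with marked areas left out. Of 93 list medians outside the random range, 82 stayed outside in the same direction with the mean over probes, 86 under normexp, 87 in the authors' table, 88 with probes well above background on every array, 89 under quantile normalization and 90 with no filter. Median centring, outlier spots kept and marked areas left out gave 92 each, and the percentile over probes well above background on all arrays 93. The draws were separate, so a list at the edge, such as MHC class II in the knockout response (-0.38 with outlier spots kept, as before), can change call by the draw alone. Calls lost include glycolysis in both responses with the mean over probes (0.20 and 0.16), B cell markers in the wild-type response under normexp (-0.23), mast cell and basophil markers there in the authors' table (-0.34) and costimulation in the knockout response with probes well above background on every array (0.32). Signal over background limits the dim genes: between genotypes with R848, 181 of 440 higher genes and 124 of 459 lower genes are lower bounds. Comparisons within a slide were not run apart, since all arrays lie on 1 slide and every comparison is within it.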

Other observations

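The tests and gene choices of this part were made after the values were seen. Some genes of blood progenitors and monocytes beyond the basophil and granulocyte lists, picked for being low, were lower in the knockout at both times. Untreated and with R848, the progenitor gene Cd34 stood at -1.86 and -1.96, the stem and progenitor factor Myb at -2.69 and -2.44, Gfi1 at -2.23 and -1.62 and the eosinophil granule gene Prg2 at -2.15 and -2.85. The monocyte genes Ly6c2 stood at -2.50 and -2.09, Ccr2, the receptor for monocyte exit from marrow, at -1.97 and -2.53 as a bound, and F13a1 at -2.01 and -2.33. Cd5l, a scavenger protein of mature macrophages, stood at -2.50 and -2.49. Since the genes named here were picked for being low, their direction is no separate evidence. The fixed list of monocyte and dendritic cell markers did not stand apart untreated (median -0.093, percentile 6.75, with 1 of 14 higher, Itgax at 1.47, and 3 lower).

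In the wild-type and knockout responses, mast cell and basophil markers had medians of -0.96 and -0.73, granulocyte markers -0.90 and -0.67 and B cell markers -0.72 and -0.47, the last inside the random range. In the wild-type response, mast cell and basophil markers lay inside it in the authors' table (-0.34). B cell markers did so under normexp (-0.23) and with probes well above background on every array (-0.11). In the responses, wild type first, Toll-like receptors and adaptors had medians of 0.22 and 0.12, although Tlr1 rose by 3.35 and 3.86. The AP-1, BATF and MAF family stood at 0.02 and 0.22, with Batf at 3.48 and 3.72, the latter from a probe in a marked area of the knockout array with R848. The knockout median stood apart from random lists, and it did so no longer under quantile normalization (0.19), in the authors' table (0.19) and with the mean over probes (0.22). Interferon regulatory factors stood at 0.15 and 0.33, the unfolded protein response at 0.15 and 0.15, alternative activation at 0.21 and -0.21 with Clec10a at -2.21 and -1.70, and osteoclast markers at 0.17 and -0.20 with Mmp9 at 2.09 and 2.77. Housekeeping genes stood at -0.13 and 0.00. The wild-type value stood apart from random lists (percentile 1.96), and median centring turned it to 0.020. It lay inside the random range with no filter and no lower bounds (-0.13) and with the mean over probes (-0.10). Markers of other cell types served as a check on the cultures: knockout minus wild type, untreated and with R848, T and NK cell markers stood at -0.06 and 0.05, B cell markers at -0.09 and 0.07, stromal and endothelial markers at -0.09 and -0.07, erythroid and megakaryocyte markers at -0.52 and 0.03, and monocyte and dendritic cell markers at -0.09 and -0.19. Of these, erythroid markers untreated and monocyte markers with R848 stood apart from random lists. Sex-linked genes stood at -0.17 and 0.01, in cultures that the labels give as male.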
